A study of Mus musculus with 8 samples.

How the data were processed

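H3R17me2a ChIP-seq was performed on cardiomyocyte nuclei from hearts of mice with floxed Carm1, injected on postnatal day 1 with a virus carrying Cre recombinase (knockout, 2 ChIP libraries) or green fluorescent protein (control, 2 ChIP libraries). Per the labels' protocols, hearts were mosaic, so that infected and uninfected cardiomyocytes were present together, nuclei positive for the cardiomyocyte marker PCM1 were sorted, chromatin was cut with micrococcal nuclease and libraries were made with a ThruPLEX kit. The 4 input libraries have no peaks of their own. Per the submitters' processing notes, FastQC, MultiQC, Bowtie2, MACS2 and DiffBind were used with the mouse build mm10; versions and settings are not given in the sources used here.

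The authors deposited a peak list for each ChIP library, without pooling replicates, per the labels. For each peak the deposited fold enrichment is the ratio of fragments at the summit to the local background, with 1 added to each. The deposited −log10 p and −log10 q are its significance over that background. The lowest −log10 p was 5.02, 5.00, 5.00 and 5.01 in control 1, control 2, knockout 1 and knockout 2. Values of different lists were not compared with each other, since they depend on each library's depth and background. The fragment number at each summit and the local background were recovered by solving the fold and the Poisson p-value together, with a tolerance of 0.01 in −log10 p. A whole fragment number was found for 99.8% to 99.9% of peaks. On 3000 simulated peaks, 97.2% of fragment numbers were recovered, and of 102 simulated summits under 20 fragments that were not whole, 2.94% were accepted. The simulation did not reach the fragment numbers of the strongest peaks or the highest local backgrounds, so recovery there was not checked. Sorting, nuclease digestion and few fragments per peak limit the lists: a weak region can be called in 1 library and missed in another by chance.

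Peaks on chromosomes 1 to 19, X and Y were used. Peaks of the 4 lists were merged into regions where they overlapped by at least 1 bp, and each region was classed by the libraries that called it. Overlap in bases (Jaccard index) was averaged within and between groups for the 3 splits of the 4 libraries. Expected overlaps came from 1000 random relocations of the peaks within their chromosome and 1000 within 50 kb. Peak number and gene shares were compared with exact two-sided permutation tests, which cannot reach a p under 0.333 with 2 libraries against 2. Control and knockout numbers are given as mean ± SD. The ratio of exclusive same-group to exclusive mixed pairs is the product of the 2 same-group counts over the geometric mean of the products of the other 2 complementary pairs. In 40000 simulated regions without a group effect its log2 was −0.01, and with 200 regions planted per group it was 0.98. Planted regions were called in both libraries of their group and in neither of the other, and the simulation was not repeated. It therefore does not show whether the ratio would detect group-specific regions that are often missed, as weak regions are in these lists.

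Genes were taken from NCBI RefSeq for GRCm38.p6, the assembly of mm10, as gene spans without strand or exons. A promoter share around transcription start sites had been planned; without strand it was replaced by the share of summits within 1 kb of either end of a gene. A region was linked to a gene when it overlapped the span or 5 kb on either side, where 5 kb upstream alone had been planned. The 241 genes of the 15 fixed lists all matched among 21887 protein-coding genes. Each list was tested in 5 classes of regions against 100000 random gene sets of the same size and length deciles (two-sided permutation p, Benjamini-Hochberg over lists within a class). In a simulation that planted 10 members of the cell cycle list, that list had an adjusted p of 3e-04 and 0 others passed.

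Groups, tests, gene lists and the rule for named genes were fixed before the data were examined. Within each class (both controls and neither knockout, both knockouts and neither control, all 4 libraries), regions were ranked by their lowest percentile of −log10 q within the lists that called them, and the genes of the highest 10 regions with a protein-coding gene were named. Members of the fixed lists in the classes exclusive to a group, at most 12 per class, and Carm1 were also named. A gene that this rule names is not reported here. Settings fixed in advance to be varied were peaks with −log10 q of at least 5, autosomes, lists of equal length, 50% reciprocal overlap, each library left out, a replicate block, other gene links and random sets without length matching. Alternatives added after the data were seen were peaks of 250 bp or wider, leaving out regions of 100-fold or more, leaving out regions with a background of 5 fragments or more, and all settings of the ratio of exclusive pairs. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Genome sequence and repeat annotation were not used here, and DiffBind output was not analysed here.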

Results

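H3R17me2a, the asymmetric dimethylation of arginine 17 on histone H3 that the arginine methyltransferase Carm1 deposits, was profiled by chromatin immunoprecipitation and sequencing in cardiomyocyte nuclei of neonatal mouse hearts. All mice carried floxed Carm1 alleles and received an adeno-associated virus on postnatal day 1, which delivered either Cre recombinase (Carm1 knockout) or green fluorescent protein (control). Each group had 2 ChIP libraries, and each ChIP library had an input library. The values analysed are the peak lists of the 4 ChIP libraries, called separately per library. The lists held 12990 peaks in control 1, 8742 in control 2, 4980 in knockout 1 and 9531 in knockout 2. They covered 4.62, 3.03, 1.83 and 3.46 Mb, with a median peak width of 297, 293, 301.5 and 301 bp. Total read numbers are unknown from the lists. The fold and q-value of each peak are the authors', relative to the background of that library, and are used here only to describe and rank peaks within a list.

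Most peaks rested on few fragments. The number of fragments at a summit, recovered from each peak's fold and p-value, had a median of 7 in control 1, control 2 and knockout 2 and of 8 in knockout 1. Summits with 10 or fewer fragments made up 87.9% of the peaks of control 1, 87.1% of control 2, 77.0% of knockout 1 and 88.5% of knockout 2. The commonest local background was 0.395, 0.470, 0.608 and 0.367 fragments, highest in knockout 1, the library with the fewest peaks. Median fold enrichment was 5.69, 5.44, 5.54 and 5.66. At this depth the lists hold presence or absence of a call, and a missing call does not show that the mark was absent.

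Carm1 was examined before other genes because it is the deleted gene. No list had a peak within 5 kb of Carm1 (mm10, chromosome 9, 21546894 to 21589467). The nearest peak lay 295 kb away in control 1, 252 kb in control 2, 8.55 kb in knockout 1 and 45.4 kb in knockout 2. Peak positions do not measure the deletion itself, so the lists neither verify nor contradict the genotype labels.

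The comparison of controls with knockouts asked whether loss of Carm1 changed where H3R17me2a was called. The highest fold enrichment was called in both groups, in Gata4, Tbx5 and Mef2c, each the gene of a cardiac transcription factor. The other 18 cardiac transcription factor genes of the fixed list had no peak above 12.5-fold, and the list did not pass its test (adjusted permutation p = 0.145). The edges of the peaks over 800-fold in these genes ranged over a median of 1 bp between lists, on 1177 to 8276 fragments per summit. Copies of spliced coding sequence in the libraries, such as plasmid or vector DNA, remain a candidate explanation, as described under other observations. These peaks therefore do not show whether the mark was retained at these genes without Carm1. Gata4 held a region at chromosome 14, 63240523 to 63241162, with a fold enrichment of 4922 in control 1, 5598 in control 2, 4285 in knockout 1 and 2447 in knockout 2. Tbx5 held a region at chromosome 5, 119882905 to 119883499, with 4782-, 5140-, 3336- and 2677-fold enrichment. Mef2c held a region at chromosome 13, 83662392 to 83662640, with 1948-, 2292-, 1770- and 1080-fold enrichment. All of these positions lie inside the annotated gene spans; exons and introns were not assigned. In number of peaks the knockouts averaged 7255.5 ± 3218 (SD, n = 2) and the controls 10866 ± 3004 (SD, n = 2), a log2 ratio of −0.63. The libraries of the groups overlapped in peak number, knockout 2 lying above control 2 (exact two-sided permutation test, p = 0.667; the smallest p this design allows is 0.333). Nothing in the labels says whether replicates came from separate animals, so p-values measure only the spread between these libraries.

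**Figure D1:**
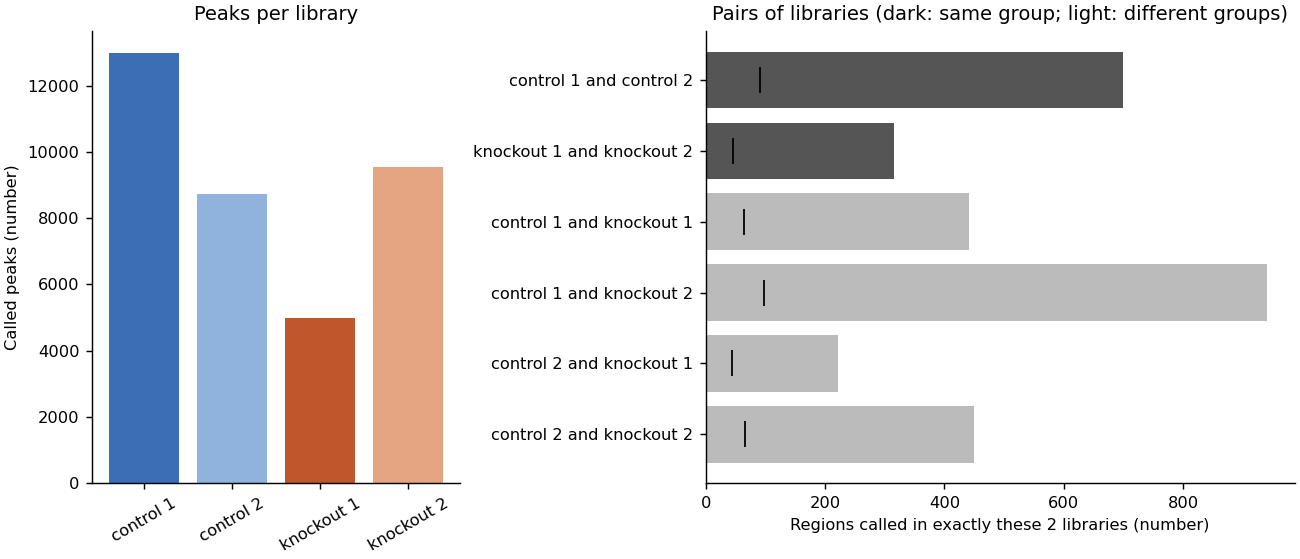
Left, number of called peaks in each of the 4 libraries, which ranged from 4980 in knockout 1 to 12990 in control 1. Right, number of regions called in exactly 2 libraries for each pair, with black ticks at the mean number after peaks were moved at random within 50 kb; control 1 with knockout 2 shared the most, 940, and control 2 with knockout 1 the fewest, 222.

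Other high-ranked regions called in all 4 libraries included further positions in the same genes. Gata4 held another at chromosome 14, 63203300 to 63203793, Tbx5 another at chromosome 5, 119871171 to 119871423, and Mef2c another at chromosome 13, 83592767 to 83592994. Each had a fold enrichment of at least 862 in every library. Serinc3, a membrane protein gene, held a region at chromosome 2, 163642988 to 163643240, with 405-, 371-, 237- and 210-fold enrichment in control 1, control 2, knockout 1 and knockout 2. Other regions of the 10 lay outside genes, 3.80 kb from Tubb3, a neuronal beta-tubulin gene (chromosome 8, 123425814 to 123426046), and 2.85 kb from the predicted gene Gm39701 (chromosome 1, 170941805 to 170942259). These regions lay 7.98 and 8.12 kb from another region, respectively, and are among the pairs described under other observations. In all, 20 regions reached 100-fold in at least 1 list, of which 18 were called in all 4. The 99th percentile of fold was 14.2 in control 1, 12.9 in control 2, 12.3 in knockout 1 and 13.4 in knockout 2, and outside the 20 regions no peak exceeded 82.4-fold.

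**Figure D2:**
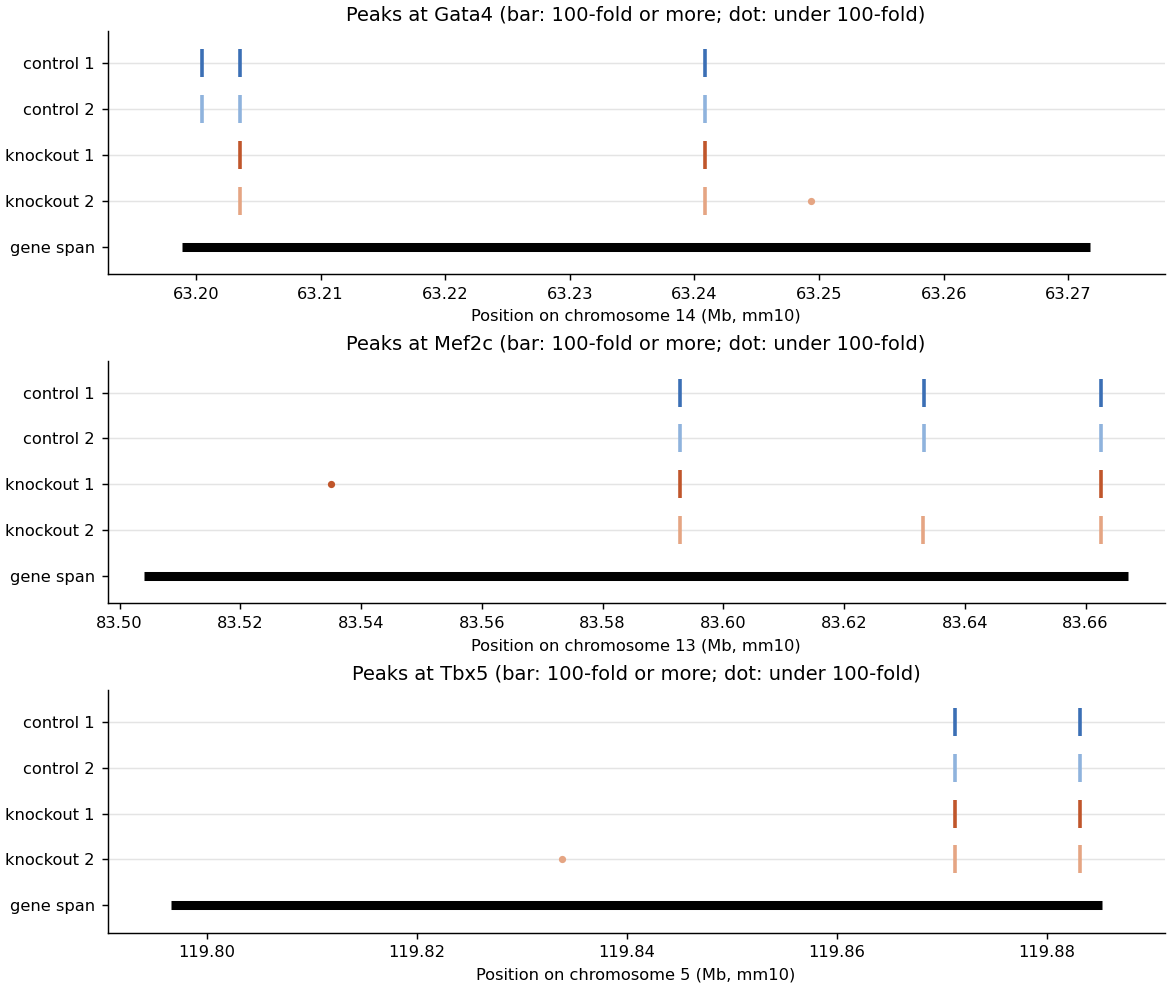
Peaks within 5 kb of Gata4, Mef2c and Tbx5 in each library along the chromosome (position in Mb, mm10). Vertical bars are peaks of 100-fold or more, dots are weaker peaks and the black line is the gene span. The bars stand at the same positions in every library that holds them; 1 Gata4 position lacks a bar in both knockouts and 1 Mef2c position lacks it in knockout 1.

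Of 28843 merged regions, 602 (2.09%) were called in all 4 libraries, 1074 in 3, 3068 in 2 and 24099 (83.6%) in 1 alone. Moving each peak at random within its chromosome gave a mean of 0.003 regions in all 4 lists over 1000 draws, and moving it within 50 kb gave 8.98 (highest 17). Recurrence rose with the number of fragments at the summit. In control 1, 12.6% of peaks with 6 or fewer fragments overlapped a peak of another library (95% Clopper-Pearson interval 11.7 to 13.6), against 94.2% of those with 30 or more (88.8 to 97.4). In control 2 these shares were 14.8% and 95.5%, in knockout 1 17.0% and 95.7%, and in knockout 2 17.0% and 93.3%. Such intervals cover counting error only. The group with 30 or more fragments held 137, 110, 117 and 89 peaks in control 1, control 2, knockout 1 and knockout 2. Regions of 100-fold or more and regions with a high local background were not left out of it. The number of regions in all 4 libraries fell to 191 when only peaks with −log10 q of at least 5 were kept, to 392 when every list was kept to its best 4980 peaks, and to 290 when shared peaks had to overlap by 50% reciprocally. It was 584 without regions of 100-fold or more and 540 without regions with a background of 5 fragments or more, settings chosen after the data were seen. In 3 libraries at a time, the number common to all was 918 without control 2 and 977 without knockout 1.

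**Figure D3:**
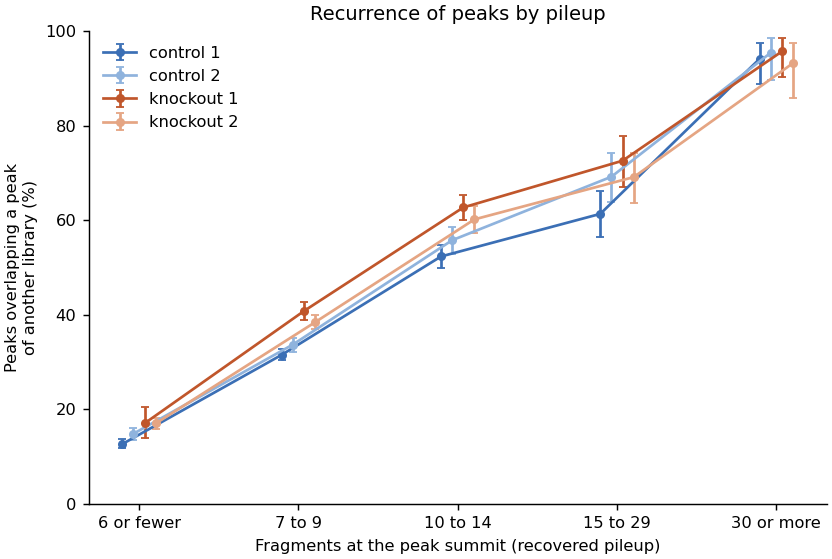
Share of the peaks of each library that overlap a peak of any other library (vertical axis, percent) by the number of fragments at the summit (horizontal axis), with 95% Clopper-Pearson intervals. The share rises in all 4 libraries, from between 12.6% and 17.0% at 6 or fewer fragments to between 93.3% and 95.7% at 30 or more.

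Regions called in both controls and neither knockout, the positions at which a loss of calls in the knockouts would appear, numbered 700. Hearts were mosaic, so the knockout libraries may include uninfected cardiomyocytes, and a loss in infected cells need not remove a call. The highest-ranked of the 700 lay in Gata4 at chromosome 14, 63200364 to 63200568, with 1675-fold enrichment in control 1 and 1770-fold in control 2. Its width of 204 to 205 bp was at or near the narrowest peak that the knockout lists hold, 209 bp in knockout 1 and 204 bp in knockout 2. The next positions were far weaker. The predicted gene Gm52512 (chromosome 2, 57217123 to 57217395) had 30.8- and 25.9-fold enrichment in control 1 and control 2. This region lay 5.04 kb from another, called in 3 libraries, and is among the pairs described under other observations. Ppat, which encodes the enzyme of the committed step of purine synthesis, had 11.5- and 17.0-fold enrichment (chromosome 5, 76936518 to 76936779). Pspc1, a paraspeckle protein gene, had 9.64- and 8.09-fold enrichment (chromosome 14, 56765118 to 56765364). Rsrc1, Inpp5a, Spink2, Coro2b and the predicted genes Gm11213 and Gm45978 completed the 10, with 9.92- to 13.8-fold enrichment. Among the genes of the fixed lists, this class also reached Dmd (dystrophin; 7.05- and 5.44-fold), Sgcd (delta-sarcoglycan; 5.72- and 6.09-fold) and Tek, an endothelial angiopoietin receptor gene (4.95- and 5.43-fold), each on 6 to 11 fragments. At other positions Dmd held peaks in both knockouts as well, and Sgcd and Tek in knockout 2. Of the other 2-library pairs, control 1 with knockout 2 shared more exclusive regions than the 2 controls, 940. The 700 became 232 with −log10 q of at least 5, 308 in lists of equal length and 453 when only peaks of 250 bp or wider were kept, the last chosen after the data were seen. Without control 1, control 2 alone held 6693 regions absent from both knockouts, without control 2, control 1 held 9999, and without knockout 2 the controls shared 1089.

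Regions called in both knockouts and neither control numbered 315. The highest-ranked was in Chl1, a neural cell adhesion gene, at chromosome 6, 103649062 to 103649277. It had 3.67-fold enrichment in knockout 1 and 3.76-fold in knockout 2 over a local background of 903 and 514 fragments, among the highest of all peaks. The other 9 had 9 to 24 fragments at the summit. A region 3.35 kb from Upk3b, a uroplakin gene (chromosome 5, 136048340 to 136048666), had 8.46- and 16.1-fold enrichment. Mpp7, a membrane scaffold gene, had 8.08- and 15.5-fold enrichment (chromosome 18, 7608898 to 7609760), and Dstyk, a protein kinase gene, 10.5- and 7.28-fold (chromosome 1, 132421400 to 132421829). Pakap, Cpne5, Aven, Cfap74, Gpc6 and Epb41l2 ranged from 5.76- to 11.8-fold. Tln2, which encodes talin 2 of the costamere, was the only fixed-list gene in this class, with 5.79- and 8.05-fold enrichment (chromosome 9, 67571618 to 67572039). The 315 became 117 with −log10 q of at least 5, and in lists of equal length 316, against 308 exclusive to controls. Without knockout 1, knockout 2 alone held 6629 regions absent from both controls, without knockout 2, knockout 1 held 2995, and without control 1 the knockouts shared 638.

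Dmd, the channel gene Kcnd2 and Erg each held a region called in all 4 lists. Zfpm2, a Gata4 cofactor gene, and the channel gene Cacna2d1 also held peaks in all 4 lists, but no region common to the controls or to the knockouts. Ttn, Xirp2 and Ryr2 held peaks in both control lists and neither knockout list, but at different positions in each, and Cacna1c and Ccnd3 in both knockout lists and neither control list, also at different positions. These genes were chosen from the fixed lists after their calls were seen. The 2 controls shared 1914 regions and the 2 knockouts 1379, against 1594 for control 1 with knockout 1, 2255 for control 1 with knockout 2, 1185 for control 2 with knockout 1 and 1575 for control 2 with knockout 2. The Jaccard index in bases was 8.99% between controls and 9.995% between knockouts, and 8.79% to 10.3% between libraries of different groups. Its mean within groups exceeded that between groups by 0.068 percentage points, the middle of the 3 possible splits (−0.574 and 0.506 for the others). With −log10 q of at least 5 this difference was −0.597 points. To allow for the different list lengths, the product of the 2 counts exclusive to same-group pairs was set over the geometric mean of the corresponding products of mixed pairs, which gave a ratio of products of 1.08 (95% interval 0.918 to 1.28, log2 0.12 ± 0.12, SE from counting). This ratio was defined after the data were examined; among peaks with −log10 q of at least 5 its log2 was 0.51 ± 0.21.

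Peaks were depleted from genes in both groups. Summits inside protein-coding genes made up 28.6% of peaks in control 1, 29.8% in control 2, 30.0% in knockout 1 and 29.9% in knockout 2, where random relocation within chromosomes gave 39.2% to 39.4%. Summits within 1 kb of either end of a gene made up 1.30%, 1.42%, 1.73% and 1.51%, and relocation gave 2.97% to 3.02%. The mean at gene ends was 1.36% ± 0.08 in controls and 1.62% ± 0.15 in knockouts (SD, n = 2 each; exact two-sided permutation test, p = 0.333, the smallest possible). Relocation did not leave out sequence to which reads cannot be aligned.

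**Figure D4:**
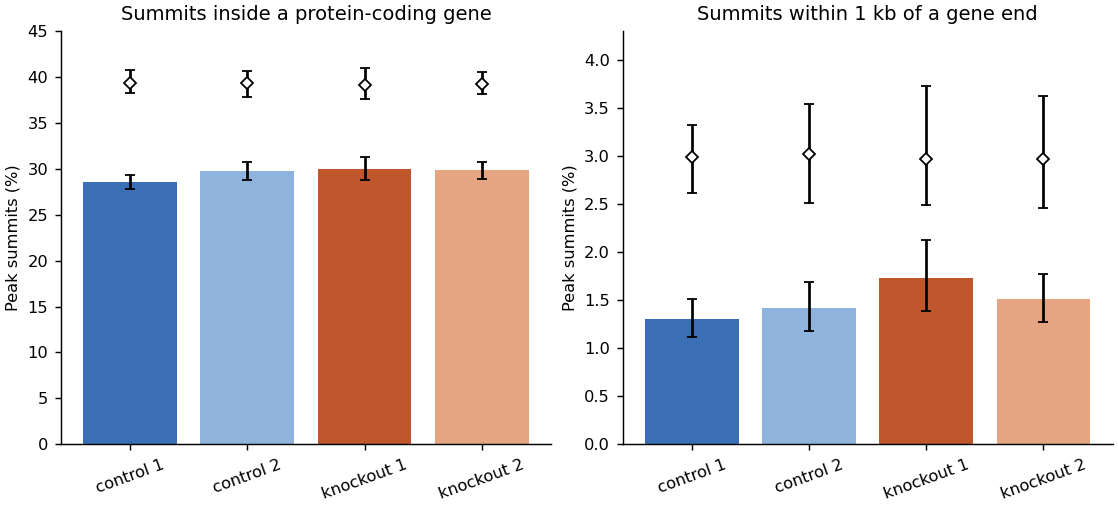
Share of peak summits (percent) inside protein-coding genes (left) and within 1 kb of a gene end (right) in each library, with 95% Clopper-Pearson intervals. Diamonds are the mean of 200 random relocations, with bars from the lowest to the highest; every bar of observed peaks lies below them.

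Fixed gene lists asked whether the mark was called at particular programmes of the cardiomyocyte. Among 21 cardiac transcription factors, 3 held a region called in all 4 libraries (Gata4, Mef2c and Tbx5), against 0.368 in length-matched random sets (two-sided permutation p = 0.00966, adjusted p = 0.145 over the 15 lists). Without regions of 100-fold or more, which removes all 3, no list reached an unadjusted p under 0.05. Among 20 genes of the intercalated disc and costamere, 4 held a region in both controls (Ctnna3, Sgcd, Sntb1 and Dmd; 1.32 in random sets, permutation p = 0.0706) and 2 held a region in both knockouts (Tln2 and Dmd). Of the 75 tests of list and class, 0 passed at an adjusted p of 0.05 in the length-matched permutation test, and 1 had an unadjusted p under 0.05. The transcription factor list passed for regions of both controls when only gene ends within 2 kb were used (adjusted permutation p = 0.0291), through 2 members. These were Gata4 and Tbx5, each by a region over 800-fold, and the Gata4 region was the one called in neither knockout.

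Counts of listed genes with a peak per library were not set against random sets, and list lengths differed, from 4980 peaks in knockout 1 to 12990 in control 1. Of 28 sarcomere genes, 4 had a peak in control 1, 3 in control 2, 0 in knockout 1 and 4 in knockout 2. None of the 10 fetal and stress genes, such as Nppa, Nppb and Myh7, had a peak in any list. For regions of both controls, length-matched random sets held 0.100 such genes on average. The counts for 16 calcium handling genes were 4, 5, 4 and 5 in control 1, control 2, knockout 1 and knockout 2, for 15 ion channel and gap junction genes 3, 2, 1 and 1, for 23 genes of fatty acid oxidation and mitochondria 4, 4, 1 and 4, and for 18 genes of glycolysis and glucose uptake 1 each. Of 20 cell cycle genes, 2, 1, 2 and 1 had a peak, and of 18 genes of arginine methylation and its coactivators 4, 0, 1 and 1. Among markers of other cell types, peaks were called at 1, 0, 0 and 1 of 12 fibroblast genes, 3, 2, 3 and 3 of 12 endothelial genes, 0, 1, 1 and 1 of 9 smooth muscle and pericyte genes, and 3, 2, 0 and 1 of 10 macrophage and immune genes. Of 16 genes of non-cardiac tissues, 0, 2, 0 and 2 had a peak.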

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

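The ratio of exclusive pairs, the gene-end share, the 250 bp minimum and the removal of high-fold or high-background regions were chosen after the data were seen, as were the strandless gene links (span with 5 kb on either side, either gene end) that replaced links to the upstream side or start; the rest was planned. The log2 ratio of peak number kept its sign throughout, from −1.10 to −0.16 with a library left out, and stayed short of any threshold, which this design cannot reach. Overlap within minus between groups turned to −0.597 points with −log10 q of at least 5. With that filter, regions exclusive to controls fell from 700 to 232, those exclusive to knockouts from 315 to 117 and those in all 4 libraries from 602 to 191, since fewer peaks entered, while the log2 ratio of exclusive pairs rose to 0.51 with an interval above 0, the cause of which was not tested; under its other settings the interval included 0. Lists of equal length gave 308 regions exclusive to controls, 316 to knockouts and 392 in all 4; a 250 bp minimum gave 453 exclusive to controls; 50% reciprocal overlap gave 290 in all 4. With a library left out, classes are defined on 3 lists, and counts ran from 923 to 9999 for controls, 446 to 6629 for knockouts and 725 to 977 for all lists. The number of gene list tests that passed was 1 with gene ends within 2 kb and 2 without length matching (intercalated disc genes in both controls, transcription factors in all 4 libraries). The former rested on regions over 800-fold in Gata4 and Tbx5, and the latter lacks the length control. The higher gene-end share in knockouts kept its sign, from 0.151 to 0.367 points with a library left out. Replicate numbers name the libraries without stated pairing: with the replicate block the log2 ratio was again −0.63, the paired values were −1.38 and 0.12 (exact sign-flip p = 1), and deviations of same-numbered libraries from their group means correlated at 0.000791 over 2662 bins of 1 Mb. Depth, mostly 10 or fewer fragments per summit, limits every count of shared regions.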

Other observations

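All tests in this part were chosen after the results were seen. Chromosome X carried 5.99 peaks per Mb in control 1, 3.83 in control 2, 2.13 in knockout 1 and 4.199 in knockout 2, against autosomal means of 4.92 ± 0.46, 3.32 ± 0.27, 1.89 ± 0.24 and 3.59 ± 0.36 (SD over 19 autosomes). It exceeded the highest autosome in control 1 and knockout 2 but not in control 2 or knockout 1. Regions with a very high local background were also common to most lists, among them chromosome 2, 98662239 to 98662953, and chromosome 9, 3009293 to 3011032, with 881 and 571 background fragments at their highest.

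The 8 regions over 800-fold in Gata4, Mef2c and Tbx5 share a shape. Enrichment common to cardiac transcription factor genes is argued against, since of the other 18 listed genes 0 held a peak of 30-fold or more and the highest, in Zfpm2, was 12.5-fold. Sequence present in many genomic copies, which raises the background as well, is argued against by a highest local background of 0.935 fragments at these regions. A candidate explanation is DNA copies of spliced coding sequence in the libraries, such as plasmid or vector DNA, for which edges should stand at fixed bases. The median range of a peak edge over the lists was 1 bp at these regions. It was 65.5 bp at the 10 regions of 100-fold or more in no protein-coding gene. At 102 other regions called in all 4 lists with at least 15 fragments it was 70.5 bp. Edges also ranged over only 2 bp at the Serinc3 region. In no protein-coding gene, the chromosome 8 regions from 123425814 and from 123433796, at up to 1072- and 1321-fold, had ranges of 3 to 6 bp. The comparison was not matched on fragment number, which was 1177 to 8276 at the 8 regions. The edge ranges therefore cannot separate DNA copies from other regions with many fragments. Whether the local background came from the input libraries is not stated in the sources used here. The recovered background was 0.367 to 0.935 fragments at the 8 regions, though it reached 1161 elsewhere in the lists. Recovery was not checked at values as high as these. A local background taken from the same ChIP library would have been raised by so many fragments. The low values thus argue that the background came from the inputs, and then also go against DNA copies present in those inputs. Exon positions and sequence were not used, so DNA copies remain a hypothesis, and site-specific enrichment at these genes alone was not excluded.

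The Gata4 region called in both controls and neither knockout may reflect the minimum peak width of each list rather than the genotype. In 3 of 3 missing calls at regions over 800-fold (this region in both knockouts, and a Mef2c region in knockout 1), the narrowest peak of the list, 209 bp in knockout 1 and 204 bp in knockout 2, was at or above the expected width of 203 to 207 bp, by only 1 bp in knockout 2. For loss of enrichment in the knockout libraries, the other 2 Gata4 regions over 800-fold were called in both knockouts, but a list gives no value where there is no call, so the explanations cannot be told apart for this region.

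Outside those genes, 65 regions reached 20-fold, and they formed 10 pairs 4 to 9 kb apart, against at most 2 in 1000 random sets of as many other regions. Of these pairs, 6 were 4.36 to 5.51 kb apart with 22.2- to 51.2-fold enrichment at their highest, and 4 were 7.90 to 8.12 kb apart, among them chromosome 8, 123425814 to 123426046 with 123433796 to 123434254, and chromosome 1, 171481419 to 171481887 with 171489317 to 171489810. A candidate explanation is terminal repeats at both ends of proviruses, whose spacing would be set by the length of the inserted element. Repeat annotation was not used, and no genotype contrast bears on it, so no biological explanation was tested.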
